A study of Saccharomyces cerevisiae with 30 samples.

How the data were processed

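Gene expression was measured in Saccharomyces cerevisiae strain S288C, a haploid laboratory strain of the alpha mating type, with an Affymetrix yeast array that also carries probe sets for another yeast species. Per the labels' protocols, cultures were started at an optical density (OD600) of 0.1, treated at 0.2 and harvested at 0.5, after about 4 h. In the long exposure they were kept with the compounds for 4.5 doublings, about 15 h. Each treatment had its own dose, an IC50 (a concentration set by its inhibition of growth), and control cultures received DMSO at 0.25%. Growth was in synthetic dextrose medium at 30 °C. Total RNA was turned into biotin-labelled cRNA and 1 array was hybridised per culture, per the labels' protocols. The 30 arrays form 10 groups of 3 cultures, in 4 experiments that each have their own DMSO group. Replicate cultures are called biological replicates in the labels, so p-values measure the spread between cultures.

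The authors deposited 1 table of 10928 probe sets by 30 arrays, and its values are intensity on a linear scale, 1 colour per array. The values of each array have a 2% trimmed mean close to 1001, which is the mark of scaling every array to one target. The software, the way probes were summarised and the background correction are not given in the sources used here. Scaling to a common mean assumes equal total signal, and a treatment that moves the most abundant messages can therefore shift all other genes of an array by a small common amount. A platform annotation table paired 5498 probe sets with exactly 1 S. cerevisiae gene, and these covered 5449 genes. Another 1746 probe sets belong to the other species, 1 has several genes and 3683 are not in that table and stay unnamed here. Gene symbols were brought up to date for 12 genes through a gene table of assembly R64, which was also used for the order of genes along each chromosome. None of its coordinates are printed. Where a gene had over 1 probe set (47 genes), the one with the highest mean was kept.

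Background was taken from the other-species probe sets. Their 95th percentile on each array was the floor, at an intensity between 11.2 and 34.5. A gene was tested if it lay above the floor on at least 3 arrays, which left 5429 genes and left out 20. Between 97.3% and 99.5% of tested genes lay above the floor on any 1 array. The number of arrays, 3 per group, limits the precision. A gene whose group lay below the floor on all 3 arrays has only a bound there, given as "at least N-fold" from the bright group's mean against the higher of the floor and the signal on each array. For named differences of effects that rest on such a group, the difference was also computed with every level raised to at least its array's floor, a step chosen after the data were seen. For 115 tested genes the probe set is of the shared type, which can hybridise with related genes.

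Values were transformed to log2(intensity + 1) and fitted with limma 3.58.1 in R 4.3.3 over all 30 arrays with a mean per group (20 residual degrees of freedom, prior 3.16). The added 1 lies far below the floor, so fitted changes that rest on a group below the floor can be overstated. With levels raised to the floor, named differences of effects of this kind shrank, except that of SET4 for E9591 against the chelators (-4.43, then -4.95). All 10 groups shared the estimate of the spread. Each treatment was compared with the DMSO arrays of its own experiment, and differences of effects between experiments were tested in the same fit. P-values of such differences measure the spread of cultures within experiments and leave out variation between experiments. P-values are two-sided limma values with Benjamini-Hochberg adjustment over the 5429 genes, and a gene was called at an adjusted p under 0.05. Errors of log2 changes are standard errors of the fit. Gene lists, 42 in all, were tested with camera (preset correlation 0.01, adjusted over the 42 lists of a comparison), and again with a correlation estimated from the data. The comparisons, lists, named-gene rule and alternatives were fixed before the data were examined. For each treatment the rule took the 10 largest rises and 10 largest falls among called genes whose 3 treated arrays all lay outside the range of their 3 controls, with the higher group mean above the floor. For differences between treatments it took 5 in each direction, and members of the gene lists could be named with their values.

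The fit was tested on simulated data made for the comparison of E9591 with DMSO at 4 h over 5429 genes. It called 82% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1, 2 or 3, and 4 of its calls (2.05%) were of unchanged genes. The changed genes were drawn from brighter genes only, so these shares do not cover dim genes. All 42 lists were called when shifted by 0.5, each at an unadjusted camera p under 0.05, and 0 when not shifted, with adjustment over the 42. The noise was independent between genes, so the preset correlation was not put to the test. The alternatives were quantile normalization, centring each array on its median, other filters on dim probe sets, a pseudocount of 16, a prior variance with a trend, array weights, a replicate block, a fit on the arrays of the compared experiments alone, a 2-fold threshold, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.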

Results

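Transcript levels were measured on 30 arrays in cultures of yeast strain S288C exposed to 4 compounds or to the solvent DMSO. E9591, named eupolauridine-9591 in the study's design, was given at 0.053 µM and liriodenine methiodide (LMT) at 2.6 µM, each for about 4 h and for about 15 h. The metal chelators bipyridyl (BIPR, 65.9 µM) and phenanthroline (PHEN, 6.2 µM) were given for about 4 h and served as references for iron deficiency. Each dose was that compound's own IC50, so the doses differ between compounds. There were 3 cultures in each of the 6 treated and 4 DMSO groups, and the pairs of arrays within a group differed by an SD of 0.109 to 0.327 on the log2 scale. No pair of arrays was identical. Changes are given on the log2 scale as the treated minus the DMSO mean of the same experiment, ± standard error, with n = 3 arrays per group.

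The first comparison set both chelators against DMSO, to define the response to iron deficiency on these arrays. The genes with the highest rises were LSO1, a small gene of the iron regulon (7.93 ± 0.42 with BIPR and 8.15 ± 0.42 with PHEN), and FIT1, a cell wall mannoprotein that retains siderophore iron (6.50 ± 0.07 and 6.43 ± 0.07). LSO1 lay below background on all 3 DMSO arrays, which makes these rises at least 52.4-fold and at least 61.2-fold. Next came DAN1, a cell wall protein of anaerobic growth (5.40 ± 0.26 and 5.92 ± 0.26). It was followed by SET4 (4.91 ± 0.48 and 5.23 ± 0.48), PBI1 (4.83 ± 0.11 and 5.05 ± 0.11), and HES1, an oxysterol-binding protein homologue (4.69 ± 0.15 and 4.82 ± 0.15). Lower in this order were YMR317W (4.35 ± 0.21 and 4.46 ± 0.21), FRE2, a ferric reductase (4.14 ± 0.07 and 4.10 ± 0.07) and the amino acid permease BAP2 (3.67 ± 0.15 and 3.95 ± 0.15). VBA3 rose by 3.85 ± 0.30 and 3.92 ± 0.30, on a probe set of the shared type. The lowest values belonged to CYC1, cytochrome c (-4.09 ± 0.12 and -3.93 ± 0.12), and CIR2 (-3.91 ± 0.09 and -3.83 ± 0.09). Next were the glutamate synthase GLT1 (-3.06 ± 0.10 and -2.98 ± 0.10), the biotin synthase BIO2 (-2.73 ± 0.11 and -2.70 ± 0.11) and the cytochrome c peroxidase CCP1 (-2.71 ± 0.07 and -2.68 ± 0.07). Further falls were those of ZPS1 (-2.36 ± 0.12 and -2.28 ± 0.12), the homoaconitase LYS4 (-2.33 ± 0.08 and -2.34 ± 0.08) and YRO2 (-2.18 ± 0.21 and -2.17 ± 0.21). Of similar size were those of the lipoate synthase LIP5 (-2.26 ± 0.10) and the diphthamide enzyme DPH2 (-2.16 ± 0.08) with BIPR, and of YER053C-A (-2.32 ± 0.30) and the succinate dehydrogenase subunit SDH2 (-2.14 ± 0.13) with PHEN.

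Of 29 tested genes of the iron regulon (targets of the iron-sensing activators Aft1 and Aft2), 27 rose and 0 fell with each chelator, with a median change of 1.29 with BIPR (camera adjusted p = 1.51e-24) and 1.18 with PHEN (2.55e-22). Besides LSO1, FIT1 and FRE2, the heme oxygenase HMX1 rose by 3.47 and 3.44. FET3 (0.23 and 0.10) and ATX1 (0.05 and 0.12) did not pass, though FET3 was called under quantile normalization (0.42 and 0.33) and without DMSO replicate C (0.42 and 0.29), and with BIPR also with array weights (0.43). All 9 tested messages bound by Cth2, a protein that speeds the decay of messages for iron-using proteins, fell with each compound (median -1.79, adjusted p = 7.24e-13, and -1.78, adjusted p = 2.75e-12). Iron-sulfur proteins fell for 16 of 19 genes and rose for 0 with each compound, with medians of -1.14 and -1.18 (adjusted p = 1.78e-16 and 4.67e-15). GLT1, BIO2, LYS4 and LIP5 were among the lowest. Genes of the respiratory chain fell for 19 of 20 (medians -0.94 and -0.94, adjusted p = 1.33e-16 and 5.35e-15). These calls held with an estimated correlation and under each scaling of the arrays. CCC1, which loads iron into the vacuole, fell by 1.46 and 1.48 on the log2 scale, but its list, the Yap5 targets, was not called (adjusted p = 0.0876 and 0.061). Nor were mitochondrial iron-sulfur cluster assembly (adjusted p = 0.183 and 0.181), cytosolic assembly (0.684 and 0.53) and, with PHEN, heme synthesis (0.061).

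Hypoxic genes rose for 8 of 14 and fell for 3 with BIPR (adjusted p = 0.016), and rose for 8 and fell for 1 with PHEN (adjusted p = 0.00244). The risers were led by DAN1, TIR4 (3.10 and 3.50) and TIR1 (2.72 and 2.77), all cell wall mannoproteins, while HEM13, a heme synthesis enzyme, fell by 1.39 and 1.37 on the log2 scale. With an estimated correlation the hypoxic calls were lost (adjusted p = 0.249 and 0.11). Ergosterol synthesis rose for 16 of 24 genes and fell for 4 with each compound (medians 0.33 and 0.33, adjusted p = 0.00796 and 0.0218), calls lost with an estimated correlation (adjusted p = 0.259 and 0.345). The 4 genes that fell were ERG1, ERG7, ERG11 and IDI1, and ERG7, the lanosterol synthase, changed by -1.31 and -1.19. IDI1 was no longer called with either compound on the arrays of its own experiment alone (-0.13 with BIPR, adjusted p = 0.1, and -0.15 with PHEN, adjusted p = 0.0537), nor with BIPR with array weights (-0.14) or without BIPR replicate A (-0.11). Ribosome assembly genes fell for 26 of 30 with each compound (medians -0.38 and -0.34, adjusted p = 1.43e-08 and 2.77e-08), which an estimated correlation did not keep (adjusted p = 0.183 and 0.199). Genes of the G1/S transition fell for 10 of 13 with each (medians -0.55 and -0.64, adjusted p = 8.02e-06 and 8.65e-07), and with an estimated correlation the adjusted p was 0.0783 for BIPR and 0.0459 for PHEN. Counts adjusted over the list alone differed by 1 or 2 genes for the respiratory chain, hypoxic, ergosterol and ribosome assembly lists and were the same for the other lists of both chelators named so far.

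In limma, 2510 genes changed with BIPR (1504 up, 1006 down) and 2656 with PHEN (1586 up, 1070 down), of which 250 and 273 changed at least 2-fold. The split depends on the scaling: under quantile normalization it was 1256 up and 1340 down with BIPR and 1278 and 1391 with PHEN, and with each array centred on its median 1223 and 1408, and 1192 and 1627. It also depends on DMSO replicate C, without which it was 1128 up and 1135 down with BIPR and 1179 and 1126 with PHEN. This array differed from the others of its group by an SD of 0.284 and 0.327 and had the lowest median log2 level of tested genes of all arrays (9.835). Of the changes of at least 2-fold, 247 of 250 and 270 of 273 were called the same way under all scalings.

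In structure, phenanthroline is bipyridyl with its rings joined by a bridge into a fused system. Between these compounds limma called 0 of 5429 genes, with 286 genes at an unadjusted p under 0.05 where 271 were to be found by chance. The 95% interval of the PHEN minus BIPR difference lay within 2-fold for 97.2% of genes and within 1.5-fold for 92.5%. For the median gene it reached 0.187 to either side. The highest absolute difference of any gene was 1.70. With array weights 21 genes were called, and without PHEN replicate A 4 were. As a list, hypoxic genes were higher with PHEN by a median of 0.18 (camera adjusted p = 9.47e-06, lost at an adjusted p of 0.0514 with an estimated correlation). Of the 14 genes 0 passed over all genes and 3 passed when adjusted over the list alone. Mitochondrial ribosomal protein genes were higher with PHEN by a median of 0.06 (adjusted p = 0.000201, and 0.889 with an estimated correlation), with 0 of 67 genes called and 1 when adjusted over the list alone. The iron regulon was lower with PHEN by a median of -0.06 (adjusted p = 0.00533), a call that ended under quantile normalization (adjusted p = 0.12) and with an estimated correlation (adjusted p = 0.745), and 0 of its 29 genes passed in either way. The changes with both compounds had a correlation of 0.959 across genes, which are not independent replicates. Simulated unchanged groups against a simulated DMSO group that they shared gave 0.504, and the covariance was 0.2716 against 0.0098. The noise was drawn independently for each gene, so deviations of the real DMSO arrays across many genes are not part of this simulation. As scaled by the authors, both raised 1344 genes (439 if the calls were independent) and both lowered 876 (198), while under quantile normalization BIPR raised only 1256 genes in all. In simulation the highest number of genes called the same way in both was 0. Part of this excess may come from the shared DMSO arrays, which are too few to be split.

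**Figure D1:**
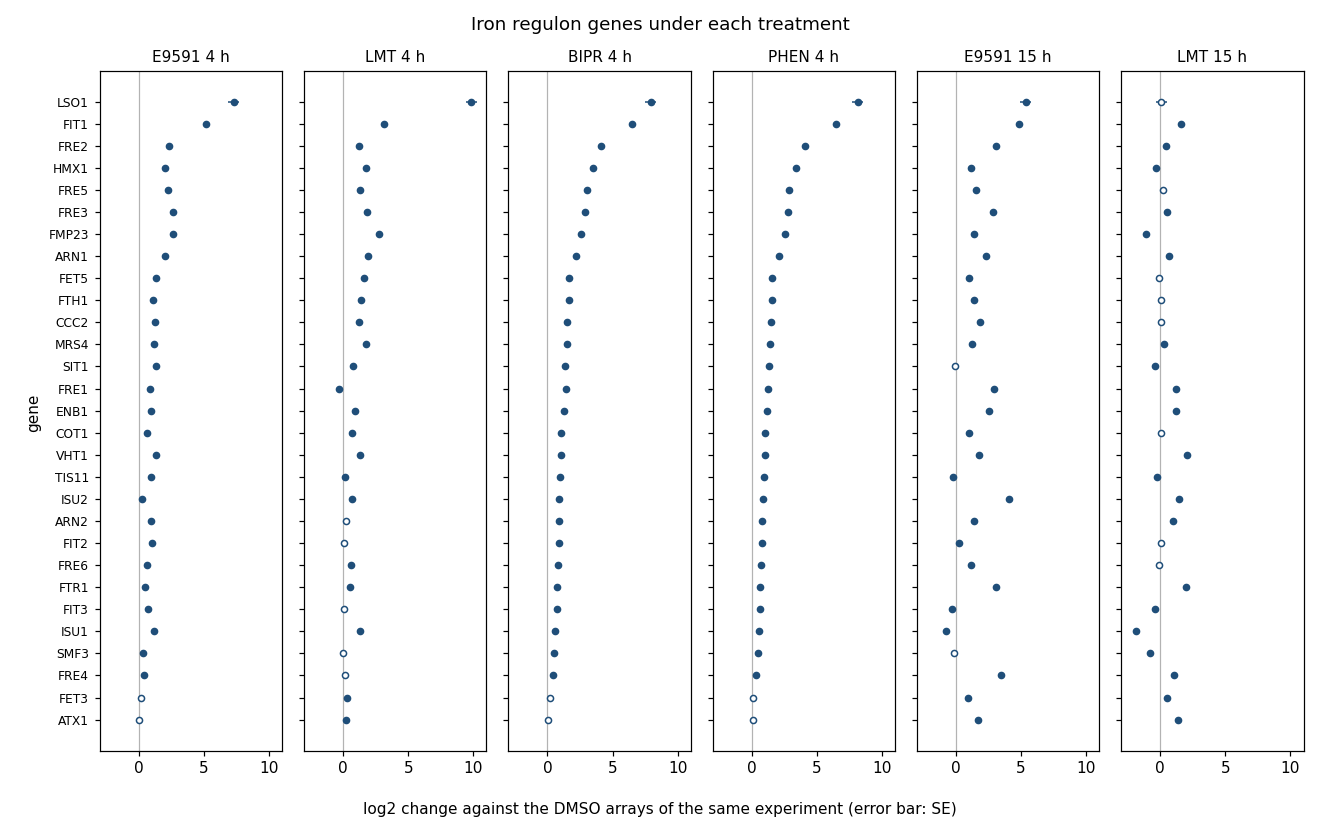
Log2 change (horizontal axis) of the 29 tested iron regulon genes (vertical axis, ordered by their mean change with BIPR and PHEN) in each of the 6 treatments, each against the DMSO arrays of its own experiment. Points are fitted means of 3 against 3 arrays, bars are standard errors, and open points did not pass the test. LSO1 and FIT1 have the highest values in the 4 h treatments, and with LMT at 15 h only 14 genes passed the test as higher.

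The second comparison asked how E9591 acts at 4 h. LSO1 rose by 7.29 ± 0.42 (at least 41.5-fold, since DMSO was below background) and FIT1 by 5.12 ± 0.07. Large rises were also found for MLS1, malate synthase of the glyoxylate cycle (4.84 ± 0.43, at least 4.11-fold), SRL4 (4.91 ± 0.39, at least 9.37-fold) and YOR186W (3.18 ± 0.22, at least 4.38-fold). So did BAP2 (3.67 ± 0.15), ECM13 (3.22 ± 0.16), the mitochondrial carnitine carrier CRC1 (3.21 ± 0.16) and NQM1, a transaldolase relative (3.10 ± 0.18), rise. VBA3 rose by 5.34 ± 0.30 on its shared probe set. Falls were small: ZPS1 changed by -0.94 ± 0.12, PHM6 by -0.78 ± 0.13, and YFR035C by -0.76 ± 0.26. SFG1 changed by -0.70 ± 0.09, YPS3 by -0.68 ± 0.10, CYC1 by -0.66 ± 0.12, the cyclin CLB6 by -0.58 ± 0.19, SCM4 by -0.56 ± 0.12, CIR2 by -0.53 ± 0.09 and ADH4 by -0.52 ± 0.09. The call of CLB6 ended without DMSO replicate A (-0.53) or E9591 replicate B (-0.51), and that of YFR035C without E9591 replicate C (-0.63). No gene fell at least 2-fold, with limma calling 614 falls in all (6 of at least 2-fold under quantile normalization and 1 with arrays centred on their median).

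Among gene groups, 27 of 29 iron regulon genes rose with E9591 and 0 fell (median 1.12, adjusted p = 1.29e-21), a call that held with an estimated correlation (adjusted p = 0.00206). The leading members were LSO1, FIT1, FMP23 (2.63) and FRE3, a siderophore reductase (2.58). Genes of gluconeogenesis and the glyoxylate cycle rose for 10 of 13 and fell for 0 (12 when adjusted over the list alone, median 1.20, adjusted p = 3.38e-06, and 0.0296 with an estimated correlation), with MLS1, CRC1, the alcohol dehydrogenase ADH2 (2.22) and the lactate carrier JEN1 (1.46) in front. All 6 tested genes that are normally expressed in cells of the a mating type rose (median 2.12, adjusted p = 3.27e-06, and 0.0119 with an estimated correlation), among them the pheromone receptor STE2 (2.19 ± 0.10), the protease BAR1 (2.41 ± 0.17) and the a-factor gene MFA2 (2.19 ± 0.15). Thiamine genes rose for 11 of 12 and fell for 0 (median 0.68, adjusted p = 2.51e-05, and 0.00758 with an estimated correlation), led by THI73 (2.10) and THI72 (1.51). Genes for cytosolic iron-sulfur cluster assembly rose for 6 of 8 (median 0.40, adjusted p = 0.00322, and 0.0886 with an estimated correlation), among them CIA2 (1.44) and NAR1 (0.92).

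Iron-sulfur proteins fell for 7 of 19 genes with E9591 and rose for 0, by a median of -0.21 (adjusted p = 0.000242, and 0.0905 with an estimated correlation), with BIO2 (-0.48) and GLT1 (-0.40) lowest and 5 genes passing when adjusted over the list alone. Of the 9 Cth2-bound messages 3 fell (median -0.21, adjusted p = 0.0192), a call that ended under quantile normalization (adjusted p = 0.166) and with an estimated correlation (adjusted p = 0.263). Ribosome assembly genes fell for 20 of 30 (22 when adjusted over the list alone, median -0.28, adjusted p = 2.32e-10, and 0.104 with an estimated correlation). Counts adjusted over the list alone were otherwise the same. In limma 2350 genes changed, 1736 up and 614 down, with 233 rises of at least 2-fold. The median of all genes moved by -0.126 under quantile normalization and by -0.159 with centring, and the split became 1004 up and 1188 down, and 1075 up and 1630 down, while 227 of the 233 were called the same way under all scalings.

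The third comparison did the same for LMT at 4 h. LSO1 rose by 9.85 ± 0.42 (at least 153-fold over a DMSO level below background), BAP2 by 5.73 ± 0.15, the stress genes HSP12 by 5.18 ± 0.22 and DDR2 by 4.75 ± 0.28, ECM13 by 4.68 ± 0.16, CRC1 by 3.83 ± 0.16, SPG4 by 3.68 ± 0.28 and BOP2 by 3.53 ± 0.11. VBA3 rose by 6.16 ± 0.30 on its shared probe set, and the spore wall gene OSW1 by 3.64 ± 0.38 (at least 2.27-fold, with DMSO below background). The falls were led by the S phase cyclin CLB6 (-3.78 ± 0.19), HO, the endonuclease of mating-type switching (-3.40 ± 0.09), the copper transporter CTR1 (-3.22 ± 0.14), the phospholipase PLB2 (-3.10 ± 0.11) and the alpha-factor gene MF(ALPHA)2 (-2.99 ± 0.14). The cohesin subunit MCD1 (-2.35 ± 0.10), the phospholipid methyltransferase CHO2 (-2.16 ± 0.08), the linker histone HHO1 (-2.11 ± 0.07), GAS3 (-2.05 ± 0.07) and RNR1, a ribonucleotide reductase subunit (-1.95 ± 0.11), followed.

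With LMT 23 of 29 iron regulon genes rose and 1, the reductase FRE1 (-0.28), fell (median 0.90, adjusted p = 1.23e-07), and the call was lost with an estimated correlation (adjusted p = 0.0791). FRE1 was no longer called without DMSO replicate A (-0.21) or B (-0.24). FIT1 (3.14), FMP23 (2.77) and ARN1, a siderophore transporter (1.87), came after LSO1. The DMSO arrays of this experiment stood furthest from the other 4 h DMSO groups, with an SD over genes of 0.539 (0.318 and 0.361 for the others) and 298 genes over 2-fold apart (68 and 98). On them the log2 level of FIT1 was 9.74 to 9.99, against 6.86 to 7.12 in DMSO beside E9591 and 7.38 to 7.51 beside the chelators, while the treated arrays were at 12.94 to 13.02 with LMT and 12.05 to 12.09 with E9591. Their median, set against the other 4 h DMSO groups, was higher by 0.34 in the iron regulon and by 0.61 in a-type genes and differed by -0.31 in Cth2-bound messages, -0.35 in iron-sulfur proteins and -0.66 in general stress genes. Of the 9 Cth2-bound messages 7 fell and 1 rose (median -0.91, adjusted p = 0.00173, and 0.134 with an estimated correlation), with HEM15 (-1.43) and CYT1 (-1.38) lowest and the aconitase ACO1 higher by 0.62. Respiratory chain genes fell for 15 of 20 and rose for 2 (16 falls when adjusted over the list alone, median -0.45, adjusted p = 0.000137, and 0.262 with an estimated correlation). Iron-sulfur proteins fell for 9 of 19 and rose for 3 (median -0.18, adjusted p = 0.0199), which neither quantile normalization (adjusted p = 0.0689) nor an estimated correlation (adjusted p = 0.262) kept. Genes for cytosolic iron-sulfur cluster assembly rose for 6 of 8 (median 0.81, adjusted p = 0.00351, and 0.0963 with an estimated correlation), again with CIA2 (1.97) and NAR1 (1.33) in front.

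Genes of gluconeogenesis and the glyoxylate cycle rose for 12 of 13 with LMT (median 1.73, adjusted p = 0.000163, and 0.085 with an estimated correlation), and all 6 a-type genes rose (median 1.65, adjusted p = 0.00174, and 0.0963 with an estimated correlation), led by MFA2 (2.58 ± 0.15). All 4 tested markers of the alpha mating type fell (median -1.34, adjusted p = 0.00151, and 0.134 with an estimated correlation), including SAG1 (-1.69 ± 0.12) and STE3 (-0.98 ± 0.09). G1/S genes fell for 12 of 13 (median -1.35, adjusted p = 1.2e-08, and 0.0323 with an estimated correlation), among them CLB6, MCD1, RNR1 and POL30, the replication clamp (-1.82). Ergosterol synthesis fell for 21 of 24 and rose for 1 (median -0.44, adjusted p = 5.86e-08, and 0.0323 with an estimated correlation), with ERG28 (-1.58) and ERG24 (-1.24) lowest. Chaperone genes rose for 13 of 17 (median 0.70, adjusted p = 0.00495, and 0.317 with an estimated correlation), including BTN2 (2.45) and HSP82 (1.86). Counts adjusted over the list alone were the same for the lists named with LMT, except where given. In limma 3558 genes changed, 2192 up and 1366 down, with 478 rises and 117 falls of at least 2-fold. The median of all genes moved by -0.115 under quantile normalization (1637 up, 1845 down) and by -0.204 with centring (1516 up, 2166 down), and 557 of the 595 changes of at least 2-fold were called the same way under all scalings.

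**Figure D2:**
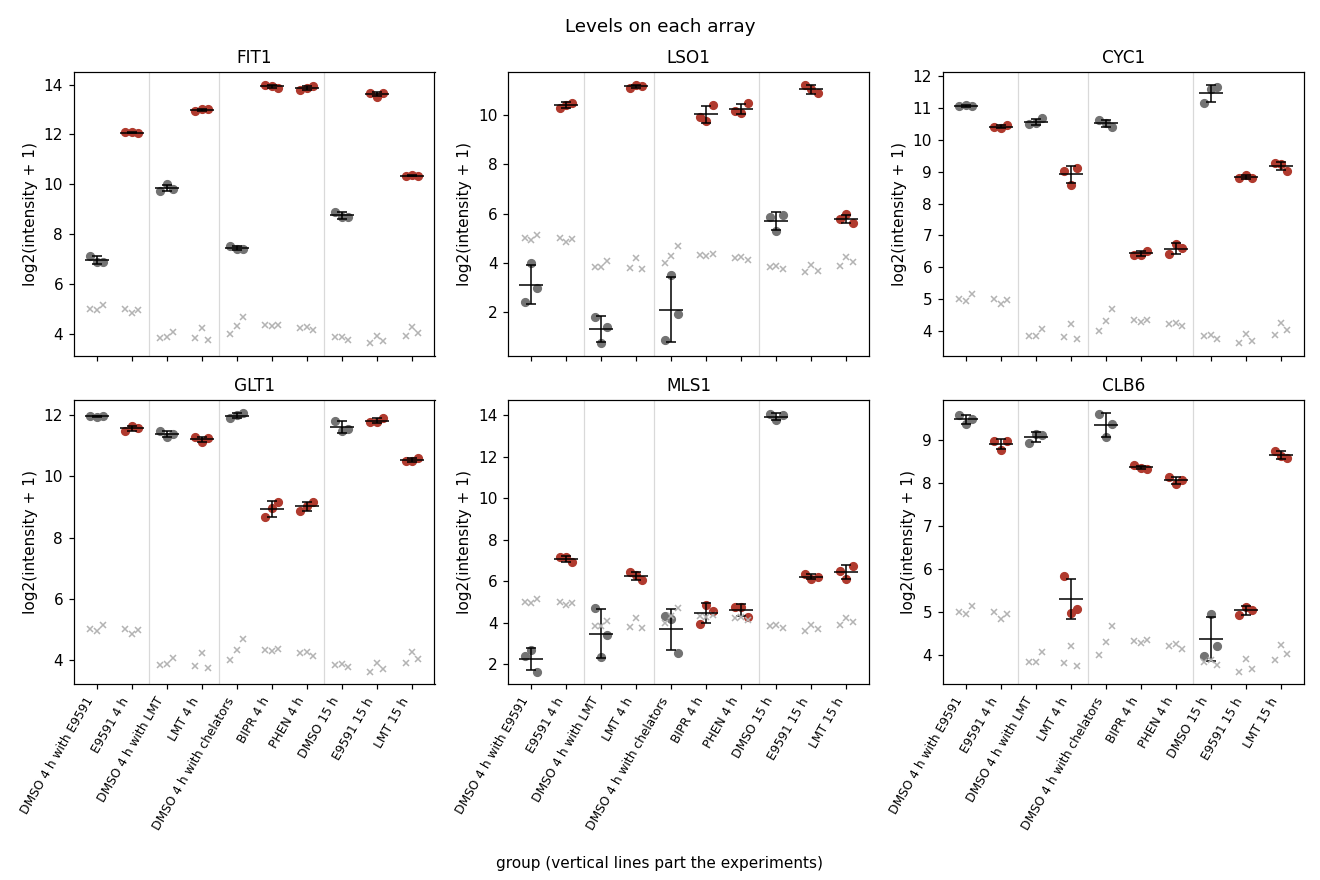
Log2(intensity + 1) on each array (vertical axis) of FIT1, LSO1, CYC1, GLT1, MLS1 and CLB6 in the 10 groups (horizontal axis), with grey points for DMSO and red points for treated arrays, black bars for the mean ± SD of 3 arrays and crosses for the background floor of each array. CYC1 and GLT1 are lowest with BIPR and PHEN, with changes of -4.09 and -3.06 for BIPR, and CLB6 is lower with LMT at 4 h by -3.78.

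**Figure D3:**
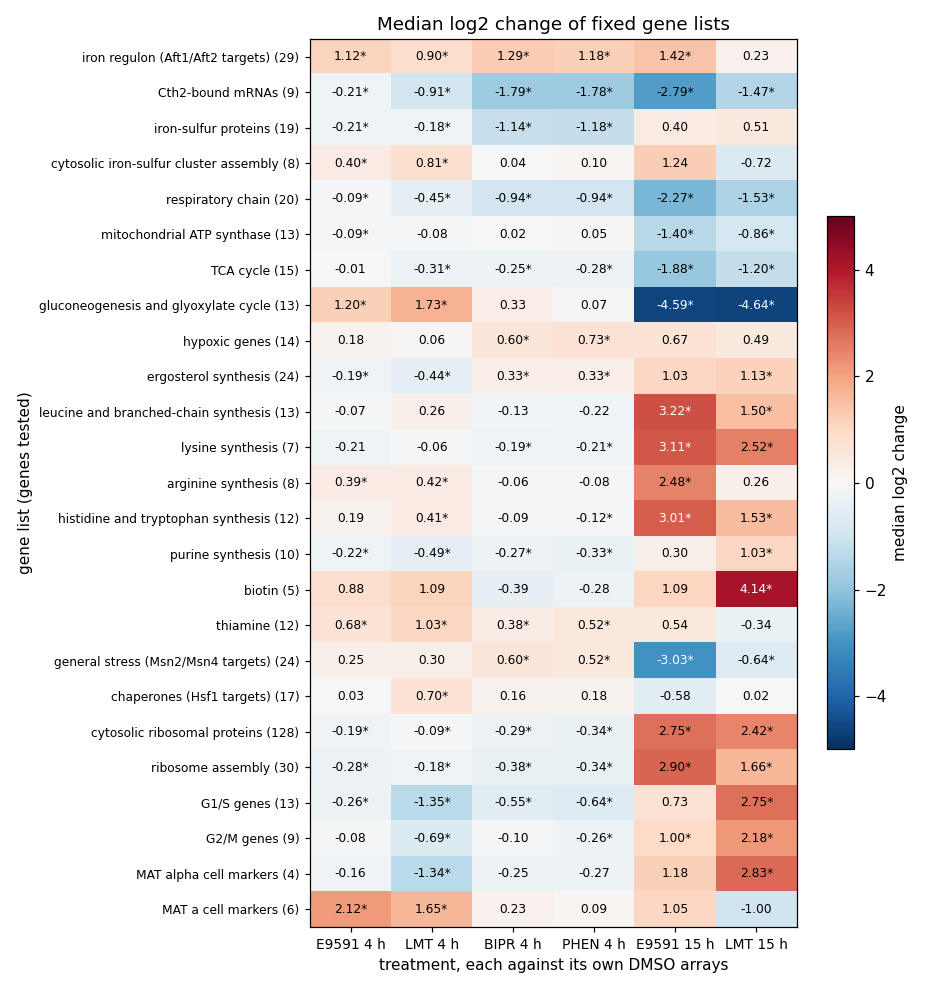
Median log2 change (colour scale and printed values) of 25 gene lists (vertical axis, genes tested in brackets) in the 6 treatments (horizontal axis), each against its own DMSO arrays. A star marks a camera adjusted p under 0.05 at the preset correlation as scaled by the authors, and the 4 h stars on small medians partly depend on that scaling, as for ribosomal proteins with LMT (-0.09), whose median turned to 0.01 under quantile normalization.

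E9591 and LMT were then set against each other at 4 h by testing the difference of their effects, each at its own dose and against its own DMSO arrays, which differed as given for LMT. CLB6 (difference 3.20 ± 0.27), CTR1 (3.0 ± 0.20), HO (2.89 ± 0.13), MF(ALPHA)2 (2.83 ± 0.19) and PLB2 (2.74 ± 0.15) were higher with E9591, and HSP12 (-2.80 ± 0.32), DDR2 (-2.71 ± 0.40), OSW1 (-2.57 ± 0.54), LSO1 (-2.56 ± 0.60) and NCA3 (-2.43 ± 0.16) were higher with LMT. The DMSO level lay below background in both experiments for LSO1 and in that of LMT for OSW1, so their differences are not exact, and with levels raised to the floor they were -1.88 and -0.51, with OSW1 no longer called (adjusted p = 0.222). The call of LSO1 ended under quantile normalization (-1.34) and that of OSW1 with a pseudocount of 16 (-0.72). G1/S genes differed for 12 of 13, all higher with E9591 (median 1.06, adjusted p = 3.57e-12, and 0.018 with an estimated correlation), where 9 of 13 also fell, but less (median -0.26, adjusted p = 0.000103, and 0.109 with an estimated correlation), and chaperone genes were higher with LMT for 10 of 17 (median -0.59, adjusted p = 8.34e-07, and 0.101 with an estimated correlation), or 12 when adjusted over the list alone. In the iron regulon 11 genes were higher with E9591 and 4 with LMT (median 0.06, adjusted p = 0.0123), but the median turned to -0.09 under quantile normalization and the call was lost there (adjusted p = 0.235) and with an estimated correlation (adjusted p = 0.347). Limma called 1409 genes, 734 higher and 675 lower with E9591 (933 and 570 with centring, 2158 genes with array weights). These calls leave out variation between the experiments of both compounds. For the median gene the 95% interval of this difference reached 0.264 to either side, and 88.9% of all intervals lay within 2-fold. As scaled by the authors, both compounds raised 1502 genes (701 if independent) and lowered 509 (154). Fewer rises can be shared under the other scalings, since E9591 raised 1004 genes in all under quantile normalization and 1075 with centring. Opposite calls were few, with 12 genes up with E9591 and down with LMT and 9 the other way.

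The effect of each compound at 4 h was then set against the mean effect of both chelators. CYC1 was higher with E9591 than with the chelators by 3.35 ± 0.16, next to SRL4 (5.79 ± 0.51), MLS1 (4.00 ± 0.57), CRC1 (3.79 ± 0.21) and ECM13 (3.43 ± 0.21), and DAN1 (-5.27 ± 0.35), YMR317W (-4.53 ± 0.28), HES1 (-4.48 ± 0.20), SET4 (-4.43 ± 0.63) and PBI1 (-4.25 ± 0.14) were lower. SRL4, MLS1 and SET4 lay below background in DMSO beside E9591 (SRL4 also with the chelators, SET4 also with E9591), so their differences are not exact, and with levels raised to the floor they were 3.52, 1.88 and -4.95. Cth2-bound messages were higher for 9 of 9 (median 1.46, adjusted p = 1.95e-11, and 0.00368 with an estimated correlation), iron-sulfur proteins for 13 of 19 (14 adjusted over the list alone, median 1.24, adjusted p = 1.02e-12, and 0.00368) and the respiratory chain for 18 of 20 (median 0.90, adjusted p = 1.02e-12, and 0.0424). Iron regulon genes were lower for 10 of 29 and higher for 1 (11 and 1 adjusted over the list alone, median -0.23, adjusted p = 1.03e-05, and 0.0835 with an estimated correlation). Limma called 1567 genes, 1024 up and 543 down (877 and 840 under quantile normalization, 837 and 893 with centring). LMT differed from the chelators in 2760 genes, 1607 up and 1153 down (1394 and 1448, and 1223 and 1576, where centring moved the median of all genes by -0.118). HSP12 (4.94 ± 0.29), ECM13 (4.88 ± 0.21), CRC1 (4.40 ± 0.21), HMS1 (4.33 ± 0.53) and SRL4 (4.33 ± 0.51) were higher and SET4 (-6.38 ± 0.63), HES1 (-5.37 ± 0.20), YMR317W (-5.06 ± 0.28), DAN1 (-5.05 ± 0.35) and PBI1 (-4.53 ± 0.14) lower with LMT. Below background lay HMS1 in both DMSO groups and with the chelators, SRL4 with the chelators and SET4 with LMT, and with levels raised to the floor their differences were 1.00, 3.73 and -4.85. Iron-sulfur proteins were higher with LMT than with the chelators for 14 of 19 and lower for 1 (16 and 1 adjusted over the list alone, median 1.11, adjusted p = 1.1e-06, and 0.0479 with an estimated correlation). The doses of the 4 compounds were not matched, and each effect rests on the DMSO arrays of its own experiment. As scaled by the authors, 880 of the genes called with E9591 and with BIPR rose in both (481 if independent) and 345 fell in both (114). For LMT and BIPR the numbers were 963 (607) and 533 (253).

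The long exposure asked how the responses stood after about 15 h, with 1 DMSO group as the control of both compounds. With E9591 the highest rises were YBR238C (7.25 ± 0.29), the adenine deaminase AAH1 (6.86 ± 0.10), YBL081W (6.28 ± 0.13) and PFK27, an enzyme that makes an activator of glycolysis (6.27 ± 0.12). The glucose repressor MIG2 (6.19 ± 0.15), the hexokinase HXK2 (5.87 ± 0.13), ANB1 (5.81 ± 0.07), the glucose transporter HXT1 (5.76 ± 0.09), CHA1 (5.47 ± 0.16) and LSO1 (5.35 ± 0.42) rose next. The lowest were SPG1 (-8.96 ± 0.25), the peroxisomal thiolase POT1 (-8.50 ± 0.28), SIP18 (-8.26 ± 0.39), SHH3 (-8.16 ± 0.68), and the acetate transporter ADY2 (-8.09 ± 0.31), before PHM7 (-7.96 ± 0.21), YKL107W (-7.92 ± 0.33), MLS1 (-7.73 ± 0.43), MBR1 (-7.60 ± 0.11) and PEX18 (-7.48 ± 0.47). With LMT, HXK2 (5.74 ± 0.13), BIO5, a transporter of biotin precursors (5.54 ± 0.23), HXT4 (5.43 ± 0.15) and AAH1 (5.35 ± 0.10) rose most. They were followed by GAS1 (5.24 ± 0.10), YBR238C (5.11 ± 0.29), INA1 (5.11 ± 0.08), GND1 (5.07 ± 0.10), RNR1 (5.05 ± 0.11) and TOS6 (5.05 ± 0.07). MLS1 (-7.50 ± 0.43) and FBP1, an enzyme of gluconeogenesis (-7.38 ± 0.33), fell most. CSM4 was at least 60.9-fold lower (fitted change -7.22 ± 0.83), with LMT below background, which leaves its rank open. YKL107W (-6.87 ± 0.33), the catalase CTA1 (-6.78 ± 0.23), YIG1 (-6.70 ± 0.20), SFC1 (-6.52 ± 0.50), SHH3 (-5.99 ± 0.68), ADY2 (-5.96 ± 0.31) and RGI2 (-5.47 ± 0.32) fell next.

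Cytosolic ribosomal protein genes rose for 128 of 128 with E9591 at 15 h (median 2.75, adjusted p = 6.34e-18) and for 126 with LMT (median 2.42, adjusted p = 2.66e-21), calls that an estimated correlation did not keep (adjusted p = 0.391 and 0.312). Ribosome assembly genes rose for 30 and 29 of 30 (medians 2.90 and 1.66, adjusted p = 7.46e-10 and 1.47e-08, and 0.201 and 0.192 with an estimated correlation). All 13 genes of gluconeogenesis and the glyoxylate cycle fell with each compound (medians -4.59 and -4.64, adjusted p = 6.91e-06 and 6.45e-07, and 0.0733 and 0.0318 with an estimated correlation). The mitochondrial ATP synthase fell for 13 of 13 with each (medians -1.40 and -0.86, adjusted p = 0.000108 and 0.000188, and 0.0128 and 0.0173). General stress genes fell for 24 of 24 with E9591 (median -3.03, adjusted p = 1.65e-06, and 0.386 with an estimated correlation), and with LMT for 18 with 4 higher (median -0.64, adjusted p = 0.0331, lost at 0.204 under quantile normalization, 0.0502 with centring and 0.654 with an estimated correlation). Iron regulon genes rose for 24 of 29 and fell for 3 with E9591 (median 1.42, adjusted p = 0.000141, and 0.201 with an estimated correlation), with LSO1, FIT1 (4.87), ISU2 (4.04) and FRE4 (3.47) leading. With LMT 14 rose and 7 fell, the list was not called (median 0.23, adjusted p = 0.235), and LSO1 was at 0.10 ± 0.42. Counts adjusted over the list alone were the same in all of these lists. The DMSO cultures of 15 h stood apart from those of 4 h: their median was lower by -2.96 in ribosomal protein genes and higher by 6.68 in gluconeogenesis and by 2.36 in general stress genes. Over all genes the SD of the log2 difference from the 4 h DMSO groups was 1.98 for DMSO at 15 h, 0.909 for E9591 and 0.983 for LMT.

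E9591 was compared with LMT directly at 15 h. HXT1 (5.92 ± 0.09), LSO1 (5.26 ± 0.42), VBA3 (4.91 ± 0.30 on its shared probe set), CHA1 (4.43 ± 0.16) and the pyruvate decarboxylase PDC5 (3.57 ± 0.15) were higher with E9591, and YOR387C (-7.84 ± 0.36), VEL1 (-6.26 ± 0.24), SPG1 (-6.24 ± 0.25), YFL012W (-5.50 ± 0.37, at least 16.3-fold, with E9591 below background) and FMP48 (-5.37 ± 0.16) were lower. Iron regulon genes were higher with E9591 for 25 of 29 and lower for 1 (median 1.26, adjusted p = 1.9e-07, and 0.0512 with an estimated correlation). Genes for cytosolic iron-sulfur cluster assembly were higher for 8 of 8 (median 1.73, adjusted p = 0.00157, and 0.0512) and arginine synthesis for 8 of 8 (median 2.15, adjusted p = 0.000102, and 0.0512). General stress genes were lower for 23 of 24 (median -2.67, adjusted p = 4.12e-07, and 0.283 with an estimated correlation), G1/S genes for 13 of 13 (median -1.78, adjusted p = 9.05e-07, and 0.0512) and biotin genes for 5 of 5 (median -3.05, adjusted p = 0.00318, and 0.0512). Counts adjusted over the list alone did not differ.

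Limma called 4770 genes with E9591 at 15 h (2481 up, 2289 down) and 4548 with LMT (2274 up, 2274 down), of which 2733 and 2011 changed at least 2-fold. The direct comparison called 4242 genes, 2097 higher and 2145 lower with E9591, and 1467 of these differed at least 2-fold. Under quantile normalization the median of all genes moved by -0.118 with LMT, and its split became 2105 up and 2586 down. The direct comparison then had 2324 genes higher and 2057 lower with E9591. The changes with both compounds had a correlation of 0.817 across genes (0.508 for simulated unchanged groups that shared a simulated DMSO group) and a covariance of 1.999 (0.0098). Both raised 1910 genes (1040 if independent) and lowered 1777 (959), and part of the excess may come from the shared DMSO arrays. Between 4 h and 15 h the change over DMSO differed for 4594 genes with E9591 (2155 higher at 15 h) and for 4493 with LMT (2067 higher, or 2250 of 4467 with centring). The correlation of the 15 h with the 4 h changes across genes was -0.199 for E9591 and -0.351 for LMT.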

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

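The tests of growth stage, of a carry-over from 4 h and of scaling for the 15 h response were chosen only after the results were seen, and so were those of glucose depletion, of a loss of the alpha programme and of growth stage for the a-type genes. The other tests here were chosen before.

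The response to E9591 differed between 15 h and 4 h in 4594 genes by a test of the difference itself. YBR238C (7.17), AAH1 (7.15), YBL081W (6.43), PFK27 (6.16) and HXK2 (6.07) had the highest fitted difference, 15 h minus 4 h, and MLS1 (-12.57), SHH3 (-9.79), SIP18 (-9.57), POT1 (-9.52) and SPG1 (-9.25) the lowest. MLS1 and POT1 lay below background in DMSO at 4 h, so their values and ranks are not exact, and with levels raised to the floor they were at -9.77 and -8.94. Lists that were higher at 15 h, by their median, were cytosolic ribosomal proteins (2.96), ribosome assembly (3.11), lysine (3.33), leucine and branched-chain (3.27), histidine and tryptophan (2.60) and arginine synthesis (1.99). So were sulfate and methionine (1.94), G1/S (1.24), G2/M (1.22) and ergosterol genes (1.08). Lists that were lower were gluconeogenesis and the glyoxylate cycle (-6.22), general stress (-3.66), Cth2-bound messages (-2.58), the respiratory chain (-2.09), the TCA cycle (-1.87), daughter-cell genes (-1.56) and the mitochondrial ATP synthase (-1.31). With an estimated correlation the call of the ATP synthase held (adjusted p = 0.0404), and the others had adjusted p values between 0.06 and 0.383. These differences also carry the shift of the DMSO arrays between both times. Against the 4 h DMSO groups, E9591 at 15 h had medians of -1.66 in G1/S, -1.17 in G2/M and -0.85 in ergosterol genes. Sulfate and methionine (-0.34), ribosomal protein (-0.19) and lysine genes (-0.02) were negative too. The other lists named as higher were positive, from ribosome assembly (0.21) to arginine synthesis (0.69). Of the lower lists, gluconeogenesis (1.59) and the ATP synthase (0.01) were positive and the others negative.

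The response to LMT differed between 15 h and 4 h in 4493 genes by the same test, where the 4 h effect rests on DMSO arrays with an SD of 0.539 from the other 4 h DMSO groups. CLB6 (8.06), RNR1 (7.00), MCD1 (6.51), HO (6.41) and HXT4 (6.36) had the highest fitted difference and MLS1 (-10.30), VBA3 (-9.77, on a shared probe set), LSO1 (-9.75), FBP1 (-9.11) and CSM4 (-8.77) the lowest. LSO1 in DMSO at 4 h, and CSM4 there and with LMT at 15 h, lay below background, so their ranks are not exact, and with levels raised to the floor they were at -7.16 and -6.02. By their median, alpha markers (4.16), biotin (3.89), G1/S (3.72), G2/M (2.83), cytosolic ribosomal proteins (2.50), lysine synthesis (2.48) and purine synthesis (1.86) were higher at 15 h. Ribosome assembly (1.83), ergosterol (1.81), sulfate and methionine (1.72), copper uptake (1.66), glycolysis (1.06) and histidine and tryptophan genes (0.71) were higher too. Gluconeogenesis and the glyoxylate cycle (-7.39), a-type markers (-2.54), thiamine (-1.42), the TCA cycle (-1.04), the respiratory chain (-1.0), the iron regulon (-0.78), the ATP synthase (-0.58) and general stress genes (-0.56) were lower. Centring ended the calls of the iron regulon (adjusted p = 0.0571), the TCA cycle (0.0571) and glycolysis (0.0558), and quantile normalization that of general stress (0.103). With an estimated correlation no list was called here, with adjusted p values between 0.0755 and 0.601. The shift of the DMSO arrays is part of these differences as well. Against the 4 h DMSO groups, only biotin (3.30) and G1/S genes (0.28) of the higher lists had positive medians with LMT at 15 h. The others ran from -0.13 (G2/M) to -1.02 (alpha markers). Of the lower lists only a-type markers were negative (-0.33), and the others ran from 0.48 (iron regulon and TCA cycle) to 2.39 (gluconeogenesis).

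E9591 and LMT changed 4770 and 4548 genes against DMSO at 15 h. The correlation of both times across genes, of which the higher was -0.199, cannot decide on a carry-over of the 4 h changes. The 15 h changes are taken against DMSO arrays that themselves differed from those of 4 h. Set against the 4 h DMSO groups, gluconeogenesis genes at 15 h had medians of 1.59 with E9591 and 2.39 with LMT. Those of the iron regulon were 1.32 and 0.48, and those of a-type genes 1.29 and -0.33. The scaling as the whole cause is argued against by the lower count under quantile normalization, 4691. A later growth stage of the 15 h DMSO cultures may account for much of the pattern. Their SD from the 4 h DMSO groups was 1.98, against 0.909 with E9591 and 0.983 with LMT. Effects of the compounds themselves at 15 h stay open beside it.

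Genes of gluconeogenesis and the glyoxylate cycle rose at 4 h with E9591 and LMT. Shared probe sets are argued against, since 0 of the members that rose were read by one, and the scaling is too, since the lowest median under the other scalings was 0.809. If the treated cultures had run further towards glucose depletion, the mitochondrial ATP synthase list should have risen as it did in DMSO at 15 h (1.19), but its median was -0.084 with the higher treatment and the SE of its mean was 0.01. As scaled by the authors, this argues against depletion as the whole cause. The SE leaves out the scaling, which moved the median gene with LMT by -0.115 under quantile normalization and by -0.204 with centring. Both shifts are larger in size than the median of the list, so the argument is made for that scaling only. With LMT the medians of the respiratory chain (-0.45, against 1.93 in DMSO at 15 h minus 4 h) and of the TCA cycle (-0.31 against 1.87) were negative, but they cannot decide. Respiratory chain genes also fell with the chelators, and the TCA list shares SDH2, SDH4 and ACO1 with the Cth2-bound messages. The TCA call also ended under quantile normalization (adjusted p = 0.174). Hexose transporters (0.04 with E9591 and 0.31 with LMT against -4.16), not called as a list (adjusted p = 0.716 and 0.405), decide nothing. Per the labels' protocols, treated and DMSO cultures of 4 h were harvested at the same OD600 of 0.5. A part played by depletion stays open beside an effect of the compounds, which the design names, since general stress genes had medians of 0.25 and 0.30 (2.36), though that list was not called either (adjusted p = 0.257 and 0.416), and ribosomal protein genes one of -0.19 with E9591 (-2.96), whose call ended under quantile normalization (median -0.017, adjusted p = 0.58).

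The a-type genes rose at 4 h with E9591 and LMT in a strain of the alpha mating type. A loss of the alpha programme in all cells as the cause for both compounds is argued against by the alpha markers, whose median was only -0.158 with E9591. A fixed share of cells of the a mating type could give each a-type gene the same ratio of LMT to E9591 increments, and the highest ratio was 1.98 times the lowest, from STE2 (0.94 ± 0.0526) to MFA2 (1.86 ± 0.20). These differ beyond their error, yet expression within such cells may also differ between treatments, which keeps this explanation open. A stage like that of the 15 h DMSO cultures is argued against, since the median of the 6 genes in DMSO at 15 h minus 4 h was -0.128 (SD 1.16 over genes, from ASG7 at -0.84 to STE6 at 2.02), against rises of 2.12 and 1.65.

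Splits of the same arrays into other groups were counted for each number of called genes. Where 6 arrays make 10 splits, these are too few for a share under 0.05. The real number and the highest of the other splits were 2350 and 4 for E9591 at 4 h, 3558 and 1 for LMT at 4 h, 4770 and 0 for E9591 at 15 h and 4548 and 0 for LMT at 15 h. They were 2510 and 3 for BIPR, 2656 and 4 for PHEN, 4242 and 1 for E9591 against LMT at 15 h, and 0 and 3 for PHEN against BIPR, where all 10 splits gave at least 0. In each of the other 7 of these comparisons, 1 split, the real one, gave as many genes.

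For differences of effects 100 splits were counted. Chance is argued against for E9591 at 15 h against 4 h (4594 genes, highest other 4358) and for LMT at 15 h against 4 h (4493 and 3879), each with 1 split as large. Both highest others kept the arrays of a treatment apart, and without such splits the highest other was 1 for E9591 and 0 for LMT. Much of each count can thus come from the change over DMSO at 1 time alone. For E9591 against the chelators (1567 and 2064) 4 of 100 splits were as large, the real one included. That share is just under 0.05 without adjustment over the differences tested, and other splits gave more genes than the real one, so chance is not excluded there. Nor can chance be excluded in this way for E9591 against LMT at 4 h (1409 and 3039, 13 splits as large) or LMT against the chelators (2760 and 3145, 6 as large). Beside the real one, all 12 as large for E9591 against LMT kept the arrays of a treatment apart, and without such splits the highest other was 1. For LMT against the chelators all 5 did so, and without such splits the highest other was 1333. For E9591 against the chelators 2 of the 3 did so, and without such splits the highest other was 1809, above the real number. The splits with 1333 and 1809 genes kept the DMSO arrays of the chelators apart, so that they exchanged BIPR with PHEN arrays in that experiment.

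A signal also appeared in 752 probe sets that the table of gene names does not list and that entered no comparison above. Of these, 47 were called with E9591 and 118 with LMT at 4 h, 253 and 237 at 15 h, 65 with BIPR and 75 with PHEN.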

How the results depend on the processing

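One alternative, raising every level to at least the floor of its array, was chosen after the data were seen, and the others before. Numbers of called genes stayed within 1.5 times under every alternative, except with array weights, a 2-fold threshold and arrays left out of PHEN against BIPR. Which genes were called changed more. Of the 2350 genes called with E9591 at 4 h, 1396 were also called under quantile normalization and 1689 with centring. For LMT at 4 h these were 2862 and 2882 of 3558. With array weights 21 genes differed between PHEN and BIPR and 2158 between the effects of E9591 and LMT at 4 h. That estimate stopped before it converged, with a weight of 0.00108 for DMSO replicate B of the chelators, and the cause was not tested. By its construction the 2-fold threshold left fewer genes: 233 and 595 for E9591 and LMT at 4 h, 2733 and 2011 at 15 h, and 250 and 273 for BIPR and PHEN. It left 1467 for E9591 against LMT at 15 h, 155 for their effects at 4 h, 2850 and 2634 for 15 h against 4 h, and 249 and 520 for E9591 and LMT against the chelators. With an estimated correlation the iron regulon was no longer called with LMT at 4 h (median 0.895, adjusted p = 0.0791) and E9591 at 15 h (1.415, adjusted p = 0.201), since camera then widens its error. Leaving out each array in turn gave 0 to 4 genes for PHEN against BIPR, with 4 without PHEN replicate A.

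Of 4372 values of single genes under the alternatives, 4348 kept direction and side of the threshold, 13 lost their call, 5 gained one and 6 turned in sign. All 6 were of genes not called. LSO1 with LMT at 15 h turned to -0.22 under quantile normalization and ran from -0.11 (without DMSO replicate B) to 0.226 (without DMSO replicate C) when arrays were left out. ATX1 with BIPR turned to -0.025 with centring, and -0.053 with array weights, and ran from -0.02 (without BIPR replicate C) to 0.092 (without BIPR replicate A). FET3 with PHEN ran from -0.01 (without chelator DMSO replicate A) to 0.291 (without replicate C). The cause was not tested.

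Replicate letters paired the arrays at most in part, with same-letter correlations of deviations from -0.091 to 0.334. Above 0.1 lay 4 of 9 same-letter pairs at 15 h, 2 of 9 with the chelators, 1 of 3 with E9591 and 0 of 3 with LMT at 4 h. Between E9591 and LMT at 15 h they were 0.048, 0.245 and 0.334, against -0.329 to 0.12 for different letters. With the letter as a replicate block 2284 genes were called with E9591 and 3553 with LMT at 4 h, and the block moved no count by over 1.5 times. Levels near the background floor limit the folds of LSO1, SRL4, MLS1, YOR186W, OSW1, CSM4, YFL012W, POT1, SET4 and HMS1. With levels raised to the floor OSW1 lost its call in the effect of E9591 against that of LMT at 4 h (-0.508, adjusted p = 0.222), and no other named gene lost one. Of 44 genes with several probe sets, between 0 and 3 had opposite calls in a treatment, and between 7 and 17 had any difference in calls between their probe sets (17 with PHEN).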

Other observations

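The ratios of list changes and the count among genes called with E9591, both in the test of response size, and the values of chromosome ends among DMSO groups and without replicate C were chosen only after the result was seen, and the other tests of this part before. Thiamine genes also rose with LMT and both chelators. With LMT 11 of 12 rose and 1, the phosphatase gene PHO3, fell (median 1.03, adjusted p = 0.000137, and 0.0286 with an estimated correlation). PHO3 was not called without LMT replicate A (-0.28). The list was led by THI73 (2.45 ± 0.22), THI72 (1.72 ± 0.13) and PET18 (1.55 ± 0.10). With BIPR 8 rose and 1 fell (median 0.38, adjusted p = 0.00584, and 0.0523 with an estimated correlation), and with PHEN 9 rose and 1 fell (median 0.52, adjusted p = 0.00244, and 0.0405 with an estimated correlation). Targets of Pho4, the activator of phosphate genes, fell for 8 of 13 and rose for 1 with BIPR (median -0.26, adjusted p = 0.00297, and 0.0523 with an estimated correlation) and fell for 7 and rose for 1 with PHEN (median -0.31, adjusted p = 0.00204, and 0.0405 with an estimated correlation). The acid phosphatase PHO5 changed by -2.00 ± 0.13 and -1.93 ± 0.13. Adjusted over the list alone, the phosphate counts were 9 down and 2 up with BIPR and 11 down and 2 up with PHEN, and the thiamine counts were the same.

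Arginine synthesis genes rose for 6 of 8 with E9591 at 4 h (median 0.39, adjusted p = 0.0055, and 0.127 with an estimated correlation) and for 5 with LMT (median 0.42, adjusted p = 0.0182, and 0.193). The mitochondrial ornithine carrier ORT1 rose by 0.94 ± 0.09 and 1.55 ± 0.09. Histidine and tryptophan genes rose for 9 of 12 with LMT at 4 h (median 0.41, adjusted p = 0.00775, and 0.262 with an estimated correlation), with TRP4 at 1.22 ± 0.07. Purine synthesis fell for 9 of 10 with LMT (median -0.49) and sulfate and methionine genes for 15 of 22 (median -0.38), each at an adjusted p of 0.000226, and of 0.134 with an estimated correlation. Counts adjusted over the list alone were the same for these lists. Biotin genes rose for 5 of 5 with LMT at 15 h (median 4.14, adjusted p = 0.00234, and 0.0969 with an estimated correlation), with BIO5 at 5.54 ± 0.23 and BIO2 at 2.82 ± 0.11.

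The fall of HO and of the alpha markers with LMT at 4 h raised the hypothesis that haploid-specific genes were repressed, as in cells that hold both mating types. Their median change was -0.269 over 9 tested genes, of which 5 fell (STE4, FUS3, FAR1, RME1 and NEJ1) and 2 rose, with a range from -0.64 to 1.04. The median did not reach the bound set beforehand, though the number of genes that fell met the other part of the prediction. As scaled by the authors, the median is far from the change of HO (-3.40), which argues against a repression of that size. Centring moved the median of all genes with LMT by -0.204, so a weaker repression stays open.

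Another hypothesis was that genes near chromosome ends, the 10 outermost annotated protein-coding genes of each arm of the 16 chromosomes of assembly R64, rose more than other genes at 4 h. Of these genes 231 were tested, and over them the median change exceeded that of random genes matched on level by 0.152 with E9591 and by 0.264 with LMT. Both had a two-sided permutation p of 1e-04, the smallest that 10000 permutations can give (adjusted p = 0.00015 over 6 treatments). The permutations drew genes and not cultures. Their p-values therefore treat neighbouring genes as independent and do not measure the spread between cultures. Rises of at least 2-fold made up 19.9% of these genes with E9591 against 3.6% of the others, and 30.3% against 7.85% with LMT, shares that were not matched on level. Shared probe sets, 51 of the 231, could contribute, and the medians, before subtracting those of matched genes, were 0.322 with E9591 and 0.49 with LMT over all 231 genes and 0.306 and 0.488 without these probe sets. The excess was 0.164 with BIPR and 0.149 with PHEN (adjusted p = 0.00015 for both), 0.243 with E9591 at 15 h (adjusted p = 0.049) and 0.165 with LMT at 15 h (adjusted p = 0.06). BIPR and PHEN share their 3 DMSO arrays and so count as 1 observation, with 0.171 and 0.15 without replicate C of that DMSO group. Each 4 h DMSO group against the other 2 gave values from -0.074 to 0.052. The values are consistent with a rise at chromosome ends at 4 h in these 3 experiments.

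A further hypothesis was that the response to LMT at 4 h is that to E9591 at a larger size. Among the 1409 genes that differed between the effects, 75.5% (1064) had fitted changes of the same sign that were larger with LMT, below the bound of 80% set beforehand. Of the others, 45 had the same sign and a larger change with E9591, and 300 had fitted changes of opposite sign. Among the 751 of the 1409 genes that were called with E9591 the share was 85.6%. The rest were 87 that changed more with E9591, some of them with opposite fitted signs, and 21 called in opposite directions. The ratio of the LMT to the E9591 mean change was 3.05 ± 0.33 for ergosterol genes but 1.28 ± 0.07 for gluconeogenesis, and 3.04 ± 0.59 and 1.19 ± 0.05 against the mean of all 4 h DMSO groups. The ratios of the iron regulon (0.87 ± 0.02) and a-type genes (0.92 ± 0.04) depend on the DMSO arrays and were 1.34 ± 0.25 and 1.28 ± 0.18 in that way. The E9591 mean change of the ergosterol genes was only -0.17, so their ratio may depend on the scaling. In size that mean is near the shift of the median gene with E9591 under quantile normalization (-0.126) and centring (-0.159). As scaled by the authors, the ergosterol and gluconeogenesis lists argue against one size factor, though 2011 of 2032 genes called with both compounds moved the same way.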
